A study of Mus musculus with 4 samples.

How the data were processed

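The data were gene expression profiles of C57BL/6 mouse cells in culture, measured on an Affymetrix whole-transcript gene array with 1 array for each of 4 groups. The groups were embryonic stem cells, osteoblasts isolated by enzyme digestion from the skull bones of newborn mice, and plastic-adherent mesenchymal stem cells (MSC) from the marrow of the thigh and shin bones, grown without or with basic fibroblast growth factor (bFGF, FGF2) at 1 ng/ml. Per the labels' protocols, 100 ng of total RNA entered the first round of cDNA synthesis and 15 µg of labelled cRNA was fragmented for hybridisation.

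The deposited table held 1 level per probe set and array. Per the submitters' processing notes the values were made with Affymetrix Expression Console and RMA, a method that corrects background, makes the distributions of the arrays alike and summarises the probes of a probe set. The log2 scale of the deposited levels was inferred from the values, which ran from 1.40 to 14.28; software versions and the genome build are not given in the sources used here. Array medians were 5.96 for embryonic stem cells, 5.93 for osteoblasts, 5.90 for MSC without bFGF and 5.84 for MSC with bFGF. RMA holds the distributions of arrays together, so a general rise or decline of transcripts per cell would not show, and levels near the floor compress differences. The number of arrays limits the precision.

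Of 35556 probe sets, the platform table gave 21789 a single gene symbol, 1621 several symbols and 12146 none; only those with a single symbol were named. A match by Entrez identifier was found for 21698 probe sets and changed 0 symbols. Each of 19938 genes took the probe set with the highest mean over the 4 arrays; 999 genes had several. A gene was counted in a comparison if its level in the higher array lay above a floor, the median of that array's probe sets with 1 symbol (6.46, 6.46, 6.29 and 6.32 in the order above). Differences are log2 level in the group named before "minus" less that in the other, and a gene was counted as higher or lower at 2-fold, a log2 difference of 1.

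With 1 array per group no test between groups was possible and there was no replicate check, so no p-value or SD between cultures is given. A pair of technical yardsticks was used instead. The spread of differences over olfactory and vomeronasal receptor genes, most of which should be silent in these cells, described noise at low levels, and the SD of differences between probe sets of the same gene described measurement noise. Neither measures variation between cultures.

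A set of 41 gene lists, 17 of them of cell type markers, was fixed before the data were examined; 773 of their 837 symbols were measured. Each list is given by the median difference of its measured genes and by its percentile among 10000 random lists of the same size matched on mean level in 20 bins. A list is described as outside the random lists when its median lay outside their central 99%. These percentiles describe these arrays and are not tests between conditions. The genes named in the text followed a rule fixed before the data were examined. It took the 12 largest differences each way for MSC with against without bFGF, the 6 largest each way for the other pairs, up to 4 members each way of any list, and a set of transcription factors, FGF receptors and FGF2. It left out predicted genes, small RNAs, and olfactory, vomeronasal, immunoglobulin and T cell receptor genes. Csf1r, H2-Ab1, Fcer1g, Lyz2, Col1a1 and Adgre1 were added after their values were seen, and Runx2, which the rule names, was not analysed here.

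The counting and list procedures were tested on simulated data, made by adding noise to the levels of the 19938 genes in MSC without bFGF. The noise, of SD 0.3 per simulated array, was set from the spread of receptor genes between the MSC arrays. Of 100 genes raised by a log2 difference of 2, 98 were counted, and of 100 lowered by 1.5, 85 were counted. Among the unchanged genes 195 were counted, 91 as higher and 104 as lower. Of 100 lists of unchanged genes, 1 lay outside the central 99% of random lists.

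The alternatives tried were the mean of a gene's probe sets, no floor or a floor at the 75th percentile, thresholds of 1.5-fold and 4-fold, centring each difference on its median, removing a loess curve (span 0.3), repeating quantile normalization, Spearman in place of Pearson correlation, lists without members under the floor or without the member with the largest difference, and random lists not matched on level. Further alternatives chosen after seeing the data left out genes higher in osteoblasts than in embryonic stem cells, or leukocyte lists. Chromosome membership came from a RefSeq gene table of the mouse assembly GRCm38.p6. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.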

Results

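Levels of 19938 genes were measured in cultured mouse cells with 1 array each for embryonic stem cells, osteoblasts, MSC grown without bFGF and MSC grown with bFGF. The stated purpose of the series was to compare the effects of bFGF on MSC of the bone marrow, with the other arrays as controls. For many genes named the level in the lower array was under the floor, and the size of such a difference depends on background.

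Genes of the monocyte and macrophage lineage stood out in MSC with bFGF. Of 26 measured genes of the macrophage list, 22 were 2-fold or more higher with bFGF than without and 0 were lower, with a list median of 2.76, above all 10000 random lists. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, was higher by 3.58, the leukocyte plastin Lcp1 by 3.38, the endotoxin co-receptor Cd14 by 3.32 and the pan-leukocyte phosphatase Ptprc (CD45) by 3.31. Not every macrophage gene was: the difference was 0.29 for the mannose receptor Mrc1 and -0.39 for the scavenger receptor Cd163, with levels of 4.92 and 4.29 under the floor in MSC with bFGF. Values for Lyz1, 0.80 higher, are uncertain because its sequence is close to that of Lyz2.

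The 12 largest differences towards MSC with bFGF were all at least 3.38. For 10 of these 12 genes the level without bFGF was under the floor, so the sizes and order of the differences depend on background. The neutrophil-attracting chemokine Cxcl2 stood at 10.49 with bFGF against 5.94 without. The leukocyte receptor Lilr4b was 4.21 higher, a value that a close family member could share. The myeloid lectin receptors Clec4e and Clec5a were higher by 3.89 and 3.56, and the adaptor Stap1 by 3.87. The interleukin 7 receptor chain Il7r was higher by 3.74, the T cell co-stimulatory ligand Cd86 by 3.61, and Tlr13, a sensor of bacterial ribosomal RNA, by 3.54. Cd72 and the myeloid inhibitory receptor Pilra were higher by 3.52 and 3.40. Of the class II antigen presentation list 4 of 11 genes were 2-fold or more higher, among them Cd86, the dendritic cell integrin Itgax (2.73) and the invariant chain Cd74 (2.53). The class II gene H2-Ab1 itself was under the floor in both MSC arrays, and the list median of 0.11 lay within the random lists.

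Genes of inflammation were higher in the same array. Of 32 chemokine and cytokine genes 10 were 2-fold or more higher and 1 was lower, with a median of 0.44 that was 1.04 without members under the floor and 0.86 with a loess curve removed. Ccl3 and Ccl4, attractants of monocytes, were higher by 2.73 and 2.70 and the inflammatory cytokine Il1b by 2.56. The NF-kB target list had a median of 0.43 with 4 of 19 genes 2-fold or more higher, including the pentraxin Ptx3 (2.21) and the regulator Nfkbiz (1.37). The interferon response list had a median of 0.46 with 3 of 22 genes at 2-fold, the RNA sensor Ifih1 (1.70), the transcription factor Irf7 (1.63) and Oasl1 (1.02). Immediate early genes were above 0 for all 20 measured members, with a median of 0.47, and Fosb was higher by 1.30, Zfp36 by 1.24 and Maff by 1.09. The macrophage list was 2.76 higher in this array, and the chemokine and NF-kB lists share 8 and 6 genes with other lists.

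Most mitosis and DNA replication genes were above 0, the larger part of them by less than 2-fold, in the comparison where the macrophage list was higher by 2.76. Of 23 mitosis genes 22 were above 0 and 7 were 2-fold or more higher, with a median of 0.87. The topoisomerase Top2a was higher by 1.86, the spindle factor Tpx2 by 1.61 and the centromeric histone Cenpa by 1.59, each from a level under the floor without bFGF. The DNA replication list had a median of 0.39 with 20 of 23 genes above 0 and 3 at 2-fold, which were Mcm3 (1.19) and, from levels under the floor, Chaf1b (1.26) and Uhrf1 (1.25). The licensing factor Cdt1 differed by -0.60. All 17 measured cholesterol synthesis genes were above 0, with a median of 0.36, and the isoprenoid enzyme Idi1 was 1.45 higher. The hypoxia and glycolysis list had a median of 0.18, with the phosphofructokinase Pfkp and the pyruvate dehydrogenase kinase Pdk1 higher by 1.60 and 1.21. Known targets of FGF signalling had a median of 0.24, above the central 99% of random lists, with 0 of 24 genes at 2-fold in either direction. Of these 24 genes 15 were above 0 and 9 below. In that list Phlda1 was higher by 0.93, Fosl1 by 0.61, Plaur by 0.52 and Lif by 0.47. The feedback inhibitor Spry4 differed by -0.73, the transcription factor Etv5 by -0.34 and Ccnd1 by -0.24. Il17rd, under the floor in both MSC arrays, differed by -0.32. These genes did not move together and 4 of the list are also in other lists, so its median shows no shared rise of FGF targets.

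Fewer genes were lower with bFGF, and the lists below the random lists were those of extracellular matrix and Wnt genes. Of 29 extracellular matrix genes 25 were below 0, with a median of -0.28 that lay below all random lists. The proteoglycan Dcn differed by -1.22 and the fibrillar collagen Col3a1 by -1.20, and these were the 2 genes lower at 2-fold. Tgfbi, a matrix protein that macrophages also make, was 2.68 higher. The Wnt list had a median of -0.31, with 12 of 27 genes above the floor and 0 at 2-fold, but once a loess curve was removed the Wnt median was -0.02. The matrix median was then -0.16, and the macrophage list lay at 2.76 in the same comparison.

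The largest difference in this direction was that of the alarmin cytokine Il33, at 8.91 with bFGF against 11.28 without, 5.2-fold lower. The sodium pump subunit Atp1b1 differed by -1.62, Neto2 by -1.56, the sarcoglycan Sgcd by -1.55 and the secretogranin Scg2 by -1.50. The semaphorin Sema7a differed by -1.44, the Wnt inhibitor Apcdd1 by -1.34 and the metalloproteinase inhibitor Timp3 by -1.29. Olig1, Kcnj12, Mfsd4a and the trypsin gene Try5 lay between -1.28 and -1.26, and Try5 belongs to a family of near-identical genes.

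Lists of the lineages that MSC can give rise to lay within the central 99% of random lists. Few of their genes had signal: 5 of 18 osteoblast, 9 of 21 chondrocyte and 6 of 19 adipocyte genes lay above the floor. The osteoblast list had a median of -0.13. The chondrocyte list had a median of -0.20, within the random lists, although 20 of its 21 genes were below 0. The adipocyte list had a median of 0.15 and Pparg, the adipocyte master regulator, differed by 0.06. The chondrocyte factor Sox9 differed by -0.73 and the osteoblast factor Sp7 by 0.11. Pparg and Sp7 were under the floor in both MSC arrays. Among stromal surface and niche genes, whose median was -0.06, the intermediate filament gene Nes was higher by 2.01, the ecto-nucleotidase Nt5e (CD73) by 1.31 and endoglin (Eng) by 1.06, while Pdgfrb differed by -1.12. Without bFGF the levels of Nes, Nt5e and Eng were 5.26, 5.68 and 5.92, under the floor, so the sizes of their differences depend on background. Lymphocyte, neutrophil, erythroid and endothelial lists had medians of -0.28, 0.03, -0.31 and -0.21, but only 0 of 16, 2 of 18, 2 of 12 and 2 of 18 of their genes lay above the floor. The FGF receptor Fgfr1 stood at 8.03 with bFGF and 7.76 without, and Fgf2 at 6.04 and 6.50. Of the 41 lists 11 lay above, 2 below and 28 within the central 99% of random lists.

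In all, 429 genes were 2-fold or more higher with bFGF and 49 were lower, of 10483 above the floor. With no floor 521 were higher and 189 lower, and with a loess curve removed 460 were higher and 32 lower. Without the genes that were 2-fold or more higher in osteoblasts than in embryonic stem cells, an alternative chosen after seeing the data, 158 were higher and 40 lower. Receptor genes differed between the arrays by -0.97 to 0.67 in the central 95% of 1194 genes, and the SD per probe set between probe sets of the same gene was 0.18. Simulated arrays, with noise of SD 0.3 set from the receptor genes, gave 91 unchanged genes as higher and 104 as lower. Only 12 of the receptor genes lay above the floor, and 0 of these passed 2-fold, so this noise was not set on genes like those counted and does not settle how many of the 49 are noise.

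**Figure D1:**
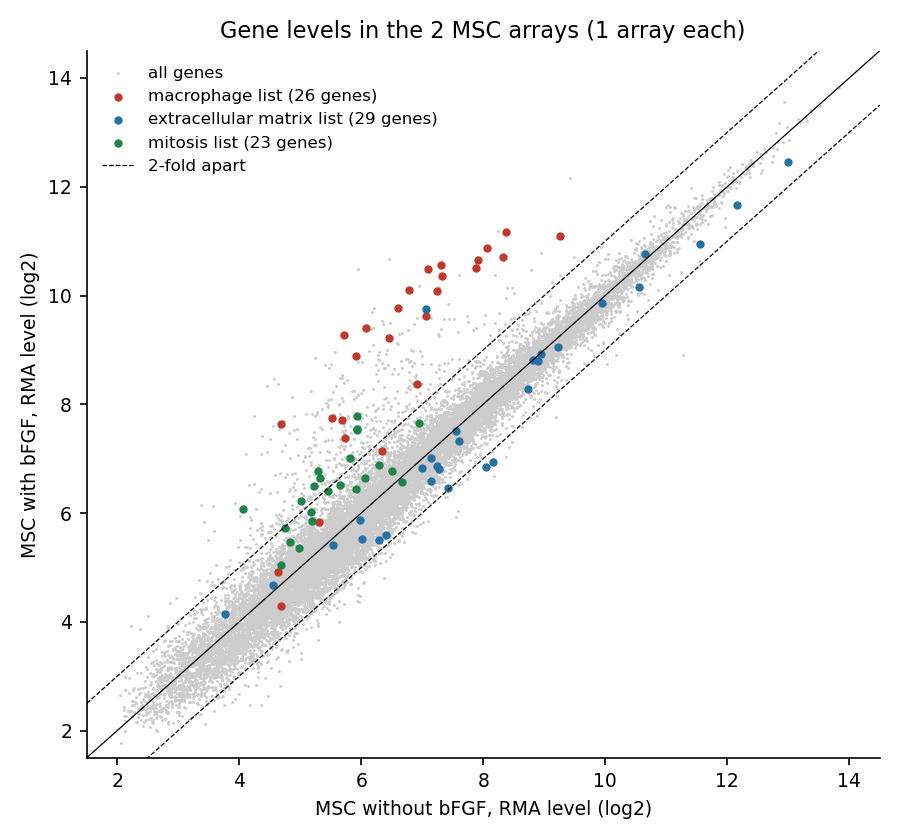
Log2 RMA level of each gene in MSC without bFGF (horizontal axis) and with bFGF (vertical axis), 1 array each, with the macrophage, extracellular matrix and mitosis lists in colour. Dashed lines mark 2-fold differences; 22 of 26 macrophage genes lie above the upper line, while 25 of 29 matrix genes lie below the line of equality.

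**Figure D2:**
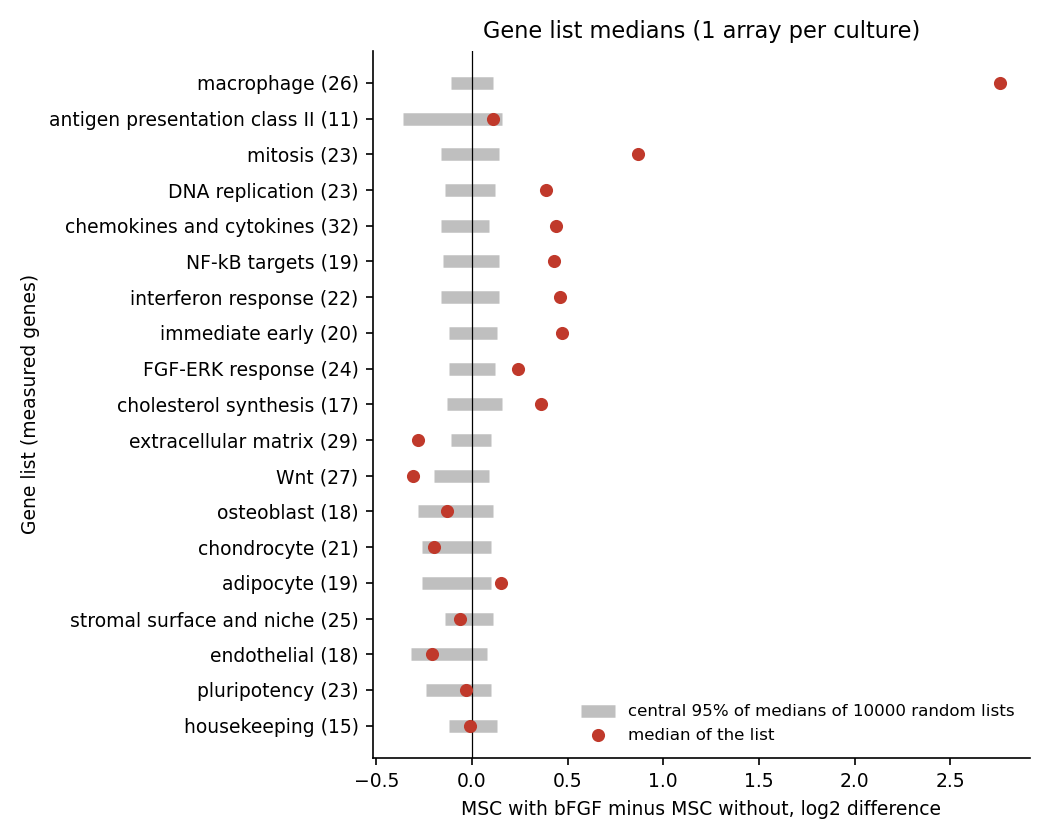
Median log2 difference, MSC with bFGF minus MSC without, of 19 of the 41 gene lists (points) and the central 95% of the medians of 10000 random lists matched on size and level (bars). The macrophage list lies at 2.76 and the mitosis list at 0.87, while the extracellular matrix and Wnt lists lie at -0.28 and -0.31.

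Compared with osteoblasts, both MSC arrays had lower levels of most matrix genes and of part of the contractile genes. In MSC with bFGF 26 of 29 matrix genes were 2-fold or more lower, with a median of -2.70, and in MSC without bFGF 24 were, with a median of -2.32. The matrix glycoprotein Thbs2 differed by -5.20, the matricellular protein Postn by -4.92 and the collagen cross-linking enzyme Lox by -4.75 in MSC with bFGF. The smooth muscle actin Acta2 stood at 12.68 in osteoblasts and at 6.58 and 6.46 in MSC with and without bFGF, and the actin-binding protein Tagln at 11.37 against 5.52 and 5.96. The pericyte and smooth muscle list had medians of -1.12 and -1.01, with 9 and 8 of 18 genes 2-fold or more lower, while Smtn and Des were above 0 in both. Against embryonic stem cells the medians of this list were -1.23 and -0.87, and that array had Acta2 at 11.91 and Tagln at 11.05. Igfbp2, a binding protein of insulin-like growth factors, differed by -5.71 and -6.04. Efemp1 and Aspn, both matrix proteins, differed by -5.72 and -5.69 in MSC with bFGF. Against osteoblasts the stromal surface and niche list had medians of -0.80 and -0.88 in MSC with and without bFGF, with 20 of 25 genes below 0 in each.

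The osteoblast array also carried high macrophage transcripts. Fcrls, a receptor-like gene of tissue macrophages, stood at 11.85 in osteoblasts and at 4.87 and 4.86 in MSC with and without bFGF. The macrophage list lay at -1.33 in MSC with bFGF minus osteoblasts and at -3.88 in MSC without bFGF minus osteoblasts, where 25 of 26 genes were 2-fold or more lower. Mrc1, Ms4a6c and Ly86 differed by -5.77, -5.77 and -5.68 in MSC without bFGF. Interferon response genes followed, with medians of -0.84 and -1.41 in MSC with and without bFGF, and mitosis genes with -1.01 and -1.95.

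Several genes with little signal in both controls were high in both MSC arrays. The large-conductance potassium channel gene Kcnma1 stood at 13.18 with bFGF and 12.85 without, against 6.05 in osteoblasts and 3.93 in embryonic stem cells. The secreted carbonic anhydrase Car6 was higher than in osteoblasts by 5.37 and 5.73 in MSC with and without bFGF, the ATP-gated channel P2rx3 by 5.42 and 5.67, and Nxf3 by 5.16 and 5.44. Dthd1 and the phosphatase Ppef1 were higher by 4.42 and 4.35 in MSC with bFGF. Il33 and Try5 were higher than in osteoblasts by 5.82 and 4.84 in MSC without bFGF. Amino acid and ER stress genes had medians of 0.90 and 0.81 in MSC with and without bFGF minus osteoblasts. Of 24 genes 11 and 10 were 2-fold or more higher, including the cystine transporter Slc7a11 (2.66 and 2.61) and the stress kinase homologue Trib3 (2.16 and 2.19).

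Some Hox genes were higher in marrow MSC than in skull osteoblasts. The Hox list, genes that mark position along the body axis, was higher in MSC by a median of 0.41 with bFGF and 0.50 without, with 7 of 30 genes 2-fold or more higher in each and 11 and 9 above the floor. Against embryonic stem cells the Hox medians were 0.00 and 0.02 in MSC with and without bFGF and -0.50 in osteoblasts, where 30 of 30 genes were below 0. Only 5 of these 30 lay above the floor in that comparison, and 2 were 2-fold or more lower. Hoxd8 was higher by 2.72 and 2.86, Hoxa9 by 1.94 and 2.10 and Hoxc9 by 1.86 and 2.05. Genes of the cranial neural crest and skull had a median of -0.80 in MSC with bFGF, where Zic1 differed by -2.92 and Six2 by -2.60. In MSC without bFGF their median of -0.36 lay within the central 99% of random lists. In each MSC array 8 of the 21 genes of this list were 2-fold or more lower than in osteoblasts and 0 were higher. In total 810 genes were higher and 1049 lower in MSC with bFGF than in osteoblasts, and 896 were higher and 1454 lower in MSC without bFGF. Few receptor genes lay above the floor, and 1 of 12 and 3 of 14 of them passed 2-fold in these comparisons, against 17.2% and 21.4% of all genes above the floor.

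**Figure D3:**
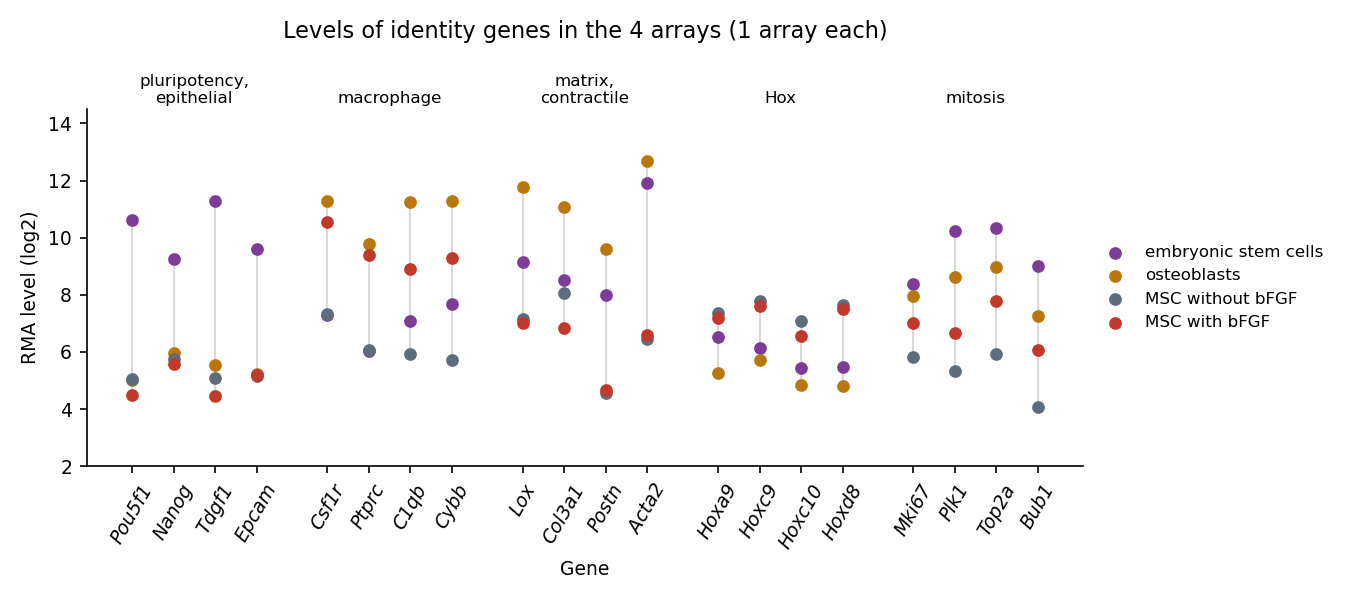
Log2 RMA levels (vertical axis) of genes from 5 kinds of list in the 4 arrays, 1 point per array; lines join the lowest and highest array. Csf1r stands at 10.56 in MSC with bFGF and 7.31 without, Pou5f1 at 10.63 in embryonic stem cells and at most 5.06 elsewhere, and Acta2 at 6.58 or less in both MSC arrays.

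Many pluripotency and epithelial genes were lower in the MSC arrays than in embryonic stem cells. The pluripotency list had medians of -2.39 and -2.46 in MSC with and without bFGF, with 15 of 23 genes 2-fold or more lower in each. Pou5f1 (Oct4) stood at 10.63 in embryonic stem cells and at 4.50 and 5.06 in MSC with and without bFGF, and Nanog at 9.24 against 5.56 and 5.76. The Nodal co-receptor Tdgf1 differed by -6.86 and -6.22. Sox2 stood at 8.79, 6.40 and 5.48 in the same order. Epithelial genes had medians of -2.72 and -2.87, with 10 of 15 genes 2-fold or more lower in each, and Cldn6 differed by -5.29 and -5.19. The 2 pluripotency genes that were 2-fold or more higher in MSC were Dppa2, by 1.83 and 1.87, and the transcription factor Klf4, by 1.28 in both arrays.

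Mitosis and cholesterol synthesis genes were lower in MSC than in embryonic stem cells, and amino acid and ER stress genes were higher. Mitosis genes had medians of -2.38 and -3.13 in MSC with and without bFGF, and all 23 were 2-fold or more lower without bFGF. Cholesterol synthesis genes had medians of -0.71 and -1.20, with 4 and 11 of 17 genes 2-fold or more lower. Amino acid and ER stress genes had medians of 1.54 and 1.48, with 18 and 16 of 24 genes 2-fold or more higher. Single genes with large negative differences in both MSC arrays were Bex1 (-6.59 and -6.43), the amino acid transporter Slc38a4 (-6.54 and -6.43) and the metalloproteinase Mmp3 (-6.29 and -6.00). The glucose transporter Slc2a3 and the carbonic anhydrase Car2 differed by -6.38 and -6.34 in MSC with bFGF, and Trh and Emb by -6.58 and -6.57 in MSC without bFGF. Kcnma1 was higher by 9.25 and 8.92, Car6 by 6.74 and 7.10, Ppef1 by 5.63 and 5.28, and the secreted peptide gene Ostn by 5.26 and 5.69. The level in the lower array was under the floor for these 4 genes, as for 74 of the 84 largest differences that the naming rule took over all pairs, so their sizes depend on background. The macrophage list was higher than in embryonic stem cells by 1.88 in MSC with bFGF and lay at -0.55 in MSC without. The matrix list lay at -1.26 and -0.98. The embryonic stem cell array itself had signal for stromal and macrophage genes, such as Col1a1 at 10.92 and Adgre1 at 9.05, which were chosen after their values were seen.

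Counts were 1236 higher and 1156 lower in MSC with bFGF than in embryonic stem cells, and 1139 higher and 1298 lower in MSC without bFGF. The median over genes above the floor was 0.12 for MSC with bFGF minus embryonic stem cells, and centring on it gave 1006 higher and 1336 lower genes.

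Matrix and macrophage genes were higher in osteoblasts than in embryonic stem cells, and pluripotency genes were lower. The osteoblast list itself had a median of 0.21, within the random lists, and the mineralization enzyme gene Alpl stood at 6.03 in osteoblasts, under the floor, against 7.64 in embryonic stem cells. Sp7 and Ibsp were under the floor in osteoblasts too, and 7 of 18 osteoblast genes lay above it in this comparison. Of the list 3 genes were 2-fold or more higher in osteoblasts, Mef2c (2.10), Dlx5 (1.52) and Msx2 (1.00), and 1 was lower. In osteoblasts 20 of 29 matrix genes were 2-fold or more higher than in embryonic stem cells, with a median of 1.52, led by the proteoglycan Fmod (4.97). Macrophage genes had a median of 3.27, with 25 of 26 at 2-fold, and Fcrls, Ms4a6b and Clec4e were higher by 5.86, 5.16 and 4.80. Aspn was higher by 5.55 and the aggrecan-cleaving protease Adamts5 by 4.95. The pluripotency list lay at -2.28, with Tdgf1 at -5.75 and Pou5f1 at -5.60. Bex1, Car2, the retinoic acid hydroxylase Cyp26a1 and Trh differed by -6.94, -6.61, -6.05 and -5.81. In total 1342 genes were higher in osteoblasts and 965 lower.

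Across 11678 genes, which are not independent replicates, Pearson's correlation was 0.945 between the MSC arrays. It was 0.817 between MSC with bFGF and osteoblasts and 0.759 between MSC without bFGF and osteoblasts. With embryonic stem cells it was 0.754 and 0.757 for MSC with and without bFGF, and 0.767 for osteoblasts. The difference between the MSC arrays correlated with osteoblasts minus embryonic stem cells at a Pearson r of 0.264 and a Spearman rho of 0.063. Of the 429 genes higher with bFGF, 271 (63.2%) were also 2-fold or more higher in osteoblasts than in embryonic stem cells, against 10.8% of genes above the floor; macrophage genes were higher in both comparisons.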

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

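Differences of 2-fold were also counted outside the genes used in the comparisons, where they were not set against noise. Of 13767 probe sets that the platform table gave no gene name or several, 4745 lay above the floor in the bFGF comparison, and 130 were 2-fold or more higher in MSC with bFGF than in MSC without, while 100 were lower. Named genes were split 429 to 49. No explanation was tested for the different split. With 1 array per group, no sample could be set against others of its group, and no contrast was repeated in another group.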

How the results depend on the processing

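No paired analysis was possible because each group had 1 array, and no replicate could be left out. Alternatives chosen after seeing the data were those without genes higher in osteoblasts than in embryonic stem cells and without leukocyte lists. Of the alternative values, 60 of the counts were within 1.5 times the reported count and 38 were not; 21 correlations kept within the bounds set and 15 moved; 541 list medians stayed, 98 moved and 5 changed sign; 243 values of named genes stayed and 9 moved; and 41 list percentiles kept their side of the central 99% without matching on level. Counts move with the threshold and floor by construction, and for other moves the cause was not tested. Low signal limits the genes under the floor.

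Genes higher in MSC with bFGF than in MSC without numbered 172 with a floor at the 75th percentile, 781 at 1.5-fold, 160 at 4-fold and 158 without genes higher in osteoblasts than in embryonic stem cells. Genes lower numbered 189 with no floor, 17 with the higher floor, 350 at 1.5-fold, 1 at 4-fold and 32 with a loess curve removed.

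With the floor at the 75th percentile, genes higher and lower numbered 498 and 593 for MSC with bFGF against osteoblasts, 577 and 825 for MSC without bFGF against osteoblasts, 759 and 554 for MSC with bFGF against embryonic stem cells, and 893 and 559 for osteoblasts against embryonic stem cells; 665 were lower in MSC without bFGF than in embryonic stem cells. At 1.5-fold they numbered, in the same order, 2146 and 1989, 2345 and 2273, 2631 and 1966, and 2492 and 2147, with 2599 and 2177 for MSC without bFGF against embryonic stem cells. At 4-fold they numbered 115 and 324, 124 and 588, 295 and 404, and 370 and 219, with 194 and 465 for MSC without bFGF against embryonic stem cells.

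With no floor the correlation was 0.973 between the MSC arrays, 0.934 and 0.911 between osteoblasts and MSC with and without bFGF, 0.915 and 0.910 between embryonic stem cells and MSC with and without bFGF, and 0.920 between the controls. With the higher floor the last 5 were 0.696, 0.611, 0.601, 0.626 and 0.609. The correlation of the MSC difference with osteoblasts minus embryonic stem cells was 0.194 with no floor, 0.301 with the higher floor, 0.063 as Spearman's rho and 0.216 without the leukocyte lists.

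For MSC with bFGF minus MSC without, removal of a loess curve gave list medians of 0.57 for DNA replication, 1.24 for mitosis, -0.16 for extracellular matrix, 0.86 for chemokines and cytokines, -0.017 for Wnt and 1.14 for Y-linked genes and Xist. Without members under the floor they were -0.38 for extracellular matrix, 1.04 for chemokines and cytokines, -0.15 for Wnt and 2.58 for Y-linked genes and Xist, where 1 gene was left. Medians that changed sign were those of chemokines and cytokines in MSC with bFGF minus osteoblasts (0.33 without members under the floor and 0.51 with loess), and, for MSC without bFGF minus embryonic stem cells, chemokines and cytokines (0.13 with loess), immunomodulatory genes (0.058 with loess) and matrix remodelling (0.041 without members under the floor).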

Other observations

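Single members of further lists differed between the MSC arrays, while the medians of these lists lay within the central 99% of random lists. Among angiogenic factors, whose list median was -0.07, the mitogens Pdgfb and Igf1 were higher with bFGF by 2.29 and 1.89 and the vasoconstrictor Edn1 by 1.28. Among immunomodulatory genes, with a median of 0.14, the galectins Lgals3 and Lgals9 were higher by 1.97 and 1.62 and the interleukin 1 receptor antagonist Il1rn by 1.72. The osteoclast fusion gene Dcstamp was higher by 2.18 in a list with a median of 0.05, and the prostaglandin D synthase Hpgds by 2.69 in the mast cell and basophil list, whose median was -0.16. Both genes were under the floor without bFGF, at 4.83 and 5.54, so these sizes depend on background. Hpgds stood at 9.10 in osteoblasts, where macrophage genes were also high. Below 0 were 14 of 22 angiogenic, 5 of 14 osteoclast and 8 of 12 mast cell and basophil genes. The urokinase Plau was higher by 2.71 among matrix remodelling genes, which had a median of -0.15. In the BMP and TGF-beta list, with a median of 0.01, the inhibitor of differentiation Id2 was higher by 1.75.

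Growth arrest genes had a median of 0.04, with 9 of 18 above 0, the cell cycle inhibitor Cdkn2b at -0.80 and the stress gene Sesn1 at 0.65. Heat shock and limb patterning lists had medians of -0.15 and -0.23, and the neural and glial list 0.12, in which the neuronal tubulin Tubb3 was 2-fold or more higher. Housekeeping genes had a median of -0.01.

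Of the tests that follow, that of scaling was chosen after the result was seen. Macrophage genes were higher with bFGF by a median of 2.76, and after centring or removal of a loess curve the lowest median was still 2.76. The median over genes above the floor was 0.0 in this comparison, so centring could hardly change the list. A loess curve follows the bulk of genes at each level, so it removes only shifts that most genes share. The difference was thus not such a shared shift, and no further conclusion on scaling is drawn. Of 35 measured pan-leukocyte genes, listed before their values were seen, 24 (68.6%) were 2-fold or more higher with bFGF, under the 75% set beforehand for more cells of the monocyte and macrophage lineage and over the 25% set against it. Of these 35 genes 33 were above 0, with a median of 1.79, and between the bounds the test does not decide. A larger share of monocyte and macrophage cells in the plastic-adherent culture cannot be told apart from myeloid genes switched on in MSC by bFGF. A percentage over 75% would not have separated these explanations either, since genes switched on in MSC could include pan-leukocyte genes. Fcer1g stood at 11.16 with bFGF and 8.38 without, Lyz2 at 10.71 and 8.32 but at 11.14 in embryonic stem cells, and Mrc1 at 4.92 and 4.63. An effect of bFGF on the cells, which the design names, stays open and untested.

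Xist, the RNA that coats the inactive X chromosome, stood at 8.09 in MSC with bFGF and 5.50, under the floor, in MSC without, so the size of the difference of 2.58 depends on background. The Y-linked genes Eif2s3y and Uty stood at 4.15 and 4.45 with bFGF and at 3.91 and 3.61 without, against 6.81 and 6.34 in osteoblasts. The osteoblast level of Uty was under the floor of 6.46. In osteoblasts and embryonic stem cells Xist stood at 7.87 and 7.23. If the cells without bFGF had 1 X chromosome fewer, genes that escape X inactivation were predicted to differ by at least 0.3. Their median over Kdm6a, Eif2s3x, Kdm5c and Ddx3x was 0.13, with values of 0.22, 0.04, 0.34 and 0.05. The median lay under the bound by 0.17, so the prediction was not met. The SD of 0.14 over these genes is a spread between different genes and not an error of their median. With 4 genes, 1 array per culture and 1 of the 4 genes past the bound, the test cannot settle a loss in the culture without bFGF alone. It says nothing of a loss in both cultures. Xist from cells of another lineage and an effect of bFGF on Xist were not tested.

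Genes of chromosomes 14 and X were lower, and those of chromosome 19 higher, in both MSC arrays than in either control. For MSC without bFGF minus osteoblasts the medians, relative to all genes, were -0.38 over 395 genes of chromosome 14, -0.34 over 352 of X and 0.20 over 422 of 19, and osteoblasts minus embryonic stem cells gave 0.00 on each. A gained or lost chromosome shared by both MSC cultures may account for this, since 3 chromosomes passed the bounds set beforehand (0.15 and the range of random gene sets) in all 4 differences between MSC and controls. Cell type genes that happen to lie there were the other explanation, and without genes 2-fold apart in any pair 2 of the 3 chromosomes, 14 and X, stayed outside the range in all 4 and 19 did so in 2 of 4, which by the bounds set beforehand left it open over the 3 together. The medians then shrank to -0.30, -0.24 and 0.12 for 14, X and 19, with cell type genes less than 2-fold apart still among those used. Leaving out genes by the size of these same differences pulls the medians towards 0 by construction, so the shrinkage speaks for neither explanation. Over all genes each of 4 parts in gene order, a division chosen after the result was seen, was negative for 14 and X and positive for 19 in all 4 differences. The shift of chromosome 14 was not equal in the MSC arrays. For MSC with bFGF minus MSC without, its median was 0.09, outside the range of random gene sets (-0.05 to 0.06). Chromosomes X and 19 lay inside their ranges there, at 0.03 and -0.01, while chromosome 18, at -0.07, lay just outside -0.06 to 0.06. No copy number was measured.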
